A study of Mus musculus with 21 samples.

How the data were processed

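Polyadenylated RNA was taken from snap-frozen whole liver of 8 NDI1 and 13 wild-type mice. Per the labels' protocols, libraries were made from 500 ng of total RNA and sequenced single-end for 100 cycles, to a stated average of 20.2 M reads. The submitters' processing notes name Trim Galore 0.6.7, STAR 2.6.1d, Salmon 1.5.2 and the mouse genome build GRCm38. Which of these tools gave the counts, and the annotation used, are not given in the sources used here. The deposited values are raw counts per row, without normalization: whole numbers whose totals differ between libraries. Salmon gives estimates that need not be whole, so the deposited counts may be rounded estimates. The mean table total of 15.3 M counts is 75.9% of the stated average. The header names the 21 libraries, each matching one mouse's label. The table does not pair rows with genes, and no name was inferred from a row's place in the table. No column belonged to another sample.

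Genotypes came from the labels. The identifier series came from the mouse numbers in the descriptions. The naming format also differs between the series, but it changes within series 2 as well. There the prefix turns from WB to WBN after wild-type replicate 7, inside a run of consecutive mouse numbers. No fit used this change of prefix. Nothing in the labels says that the series are sequencing batches. The comparisons were NDI1 against wild-type, series 2 against series 1, and their interaction. Each was tested with edgeR 4.0.16 in R 4.3.3: filterByExpr with the genotype, TMM scaling, robust dispersion, the quasi-likelihood F test with the other factor as a term, and Benjamini-Hochberg adjustment over the 11814 rows tested, with a threshold of 0.05. These rows held 99.9% of the counts in the library where they held the least. Fold changes of named rows are unshrunk model coefficients, with SEs from the model's information matrix and the moderated quasi-dispersion and 95% intervals from its t distribution. Log2 CPM for the principal components used a prior count of 2; the correlation between the series used log2(CPM + 0.5). P-values for single values are exact permutation tests, enumerated within series where stated. Python 3.11.15 with scipy 1.17.1 was used for these.

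The edgeR steps were tested on simulated counts drawn with the real means, dispersions and library sizes, with 50 rows changed at each of 4 fold sizes: 1.5-, 2- and 4-fold, and a smaller one of which 12% were recovered between genotypes. In the genotype simulation 3 of 120 calls were false, in the series simulation 7 of 140 and in the interaction simulation 4 of 63. The search for partner rows recovered 20 of 20 planted pairs among 5040 simulated rows. The planted partners mirrored their rows with little noise.

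Libraries of one genotype differed from each other by more than sampling noise: over 106 pairs, the chi-square statistic per row was between 11.8 and 133, so none were counted as duplicates.

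The rule for named rows, the lists and most alternatives were fixed before the data were examined. The rule took the NDI1 row if one was named, the 12 largest changes in each direction among rows past the threshold, up to 4 members of each fixed list, 10 genes of interest, and, with fewer than 10 rows past the threshold, the 10 with the smallest p. Without gene names it reduced to the last part, and at most 2 rows are named in each direction. The NDI1 level and the tests of gene lists, chromosome positions and a sex index that were planned need gene names and were not run. The alternatives changed the scaling, the low-count filter, the tool (DESeq2 1.42.0 on the 23772 rows with any count, with its own filtering, and limma 3.58.1 voom with sample quality weights), the covariates (with sva 3.50.0 for 1 surrogate variable), the threshold and the libraries. Beside these, DESeq2 on the rows edgeR tested, limma-voom without the weights, runs of consecutive mouse numbers as terms, the omission of runs without NDI1 mice, counts at an unadjusted p and the alternatives for single rows were added after seeing the data. In all, 39 alternatives of the genotype fit and 2 other thresholds were run. Nothing states whether libraries share a litter or a harvest day, so p-values measure the spread between these mice. Intervals and floors cover counting error, and in the models the spread between mice, only.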

Results

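Liver RNA was sequenced from 21 C57BL/6J mice aged 12 to 16 weeks and fed standard chow, 8 labelled NDI1 and 13 labelled wild-type. NDI1 is the yeast mitochondrial NADH dehydrogenase, an enzyme that passes electrons from NADH to ubiquinone without the mammalian respiratory complex I. The study asked whether metformin lowers blood glucose by way of complex I, and the stated purpose of the sequencing was to look for NDI1 transcript in the liver. None of the libraries is labelled with a metformin treatment. The mice carry identifier numbers that fall into 2 series. Series 1, with the lower numbers, holds NDI1 replicates 1 to 5 and wild-type replicates 1 to 5. Series 2, with the higher numbers, holds NDI1 replicates 6 to 8 and wild-type replicates 6 to 13. Each library carries its own mouse's number.

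The count table holds 45708 rows and does not pair them with gene names or identifiers, so rows are named below by their number from the top of the table. At most a pair of rows is named in each direction, and the pathway and cell type lists fixed beforehand were not tested. Library totals ran from 10736521 to 20460926 counts, or 10.7 M to 20.5 M. Series 1 was deeper, at 18.6 ± 0.874 M (SD, n = 10) against 12.3 ± 1.05 M (SD, n = 11) in series 2. NDI1 libraries averaged 16.3 ± 3.84 M (SD, n = 8) and wild-type libraries 14.7 ± 3.05 M (SD, n = 13). Of all rows, 21936 were at 0 in every library, and 11814 were abundant enough to be tested. The single most abundant row took 5.42 ± 0.659% of the counts (SD, n = 21).

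Row 45708, the last row of the table, separated the genotypes completely. It was counted in all 8 NDI1 libraries and had 0 counts in all 13 wild-type libraries, out of 191 M wild-type counts in total. Its counts in NDI1 replicates 1 to 8 were 247, 259, 611, 444, 571, 138, 27 and 94. Its mean in the NDI1 libraries was 16.8 ± 10.7 CPM (counts-per-million of the library total; SD, n = 8), with a range of 2.33 to 32.5. The floor that 0 counts allow over the wild-type group is 3 counts or 0.0157 CPM. Set against it, the mean level was at least 1067-fold higher in NDI1 livers. Against the wild-type floor of its own series, the NDI1 mean was at least 685-fold higher in series 1 and 239-fold higher in series 2. These floors cover counting error only. An exact permutation test of the difference in means, with genotypes permuted within the identifier series, gave a two-sided p of 2.4e-05 over 41580 regroupings, which is the smallest it can give. The row was named for its small p between the genotypes, and complete separation fixes the permutation p at this minimum. That p is not adjusted for the choice among the rows tested. In edgeR's quasi-likelihood test across all tested rows the adjusted p of row 45708 was 0.000128. The table does not name this row, so it is reported by number and not as NDI1.

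The level of row 45708 was uneven among the NDI1 mice. It averaged 22.5 ± 9.04 CPM in the 5 NDI1 libraries of series 1 and 7.17 ± 4.27 CPM in the 3 of series 2, a 3.14-fold ratio of means. All 5 series 1 values lay above the highest series 2 value of 10.4 CPM. The difference passed an exact two-sided permutation test over 56 regroupings (p = 0.0357), which treats the mice as exchangeable. The 3 NDI1 mice of series 2 belong to 1 run of consecutive mouse numbers. In series 1 NDI1 replicates 1 and 2, each from a separate run, measured 12.1 and 14.3 CPM. Replicates 3 to 5, from another run, measured 32.5, 24.3 and 29.4 CPM. A difference between the series therefore cannot be told apart from differences between runs. NDI1 replicate 7 was the lowest of the 8, at 2.33 CPM.

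**Figure D1:**
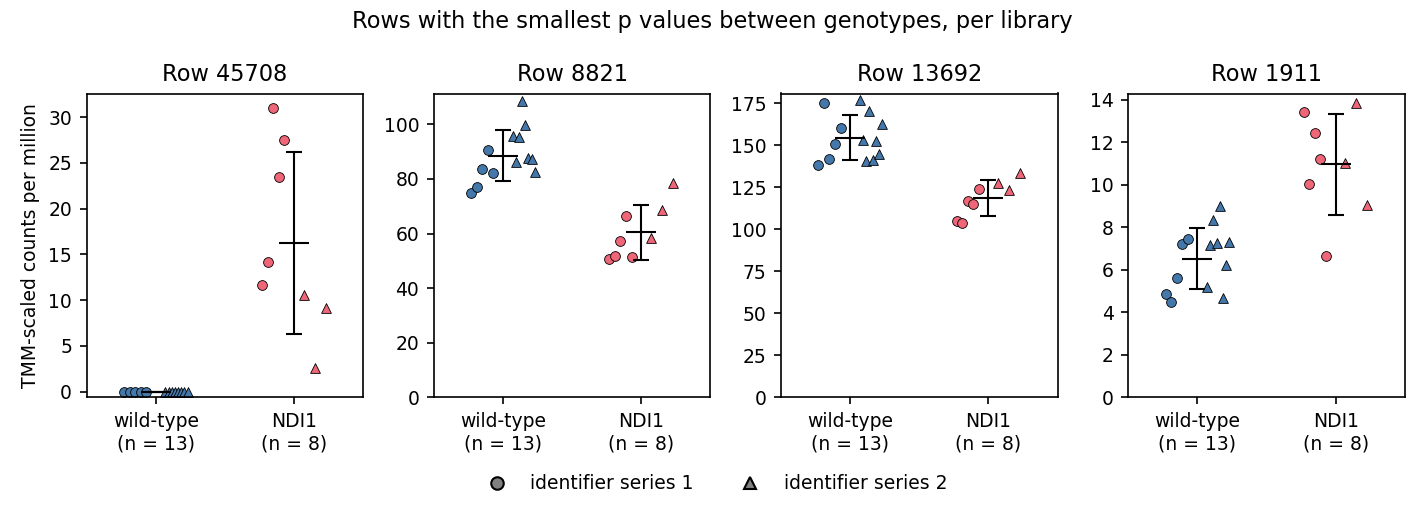
TMM-scaled CPM (vertical axis, linear) of rows 45708, 8821, 13692 and 1911 in the 13 wild-type and 8 NDI1 libraries, with circles for identifier series 1 and triangles for series 2. Horizontal bars are means and error bars are SDs; row 45708 is at 0 in every wild-type library, and in row 13692 the 8 NDI1 values lie below every wild-type value on this scale.

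Outside row 45708, few rows passed the threshold in the comparison of NDI1 with wild-type liver. Of 11814 rows tested, 3 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test with the identifier series as a term. Row 45708 was higher in NDI1 livers, and rows 8821 and 13692 were lower. Row 8821 fell by 29.3%, from 88.5 ± 9.36 TMM-scaled CPM in wild-type livers (SD, n = 13) to 60.4 ± 10.0 in NDI1 livers (SD, n = 8). Its log2 fold change was -0.50 (SE 0.069, 95% confidence interval -0.64 to -0.36, edgeR adjusted p = 0.00189). Of its 8 NDI1 values, 7 lay below the lowest wild-type value, on TMM-scaled CPM and on CPM of the library total alike. Row 13692 fell by 22.4%, from 155 ± 13.5 TMM-scaled CPM (SD, n = 13) to 119 ± 10.5 (SD, n = 8). On that scale all 8 NDI1 values lay below every wild-type value, and on CPM of the library total 7 of 8 did. Its log2 fold change was -0.37 (SE 0.060, interval -0.49 to -0.24, edgeR adjusted p = 0.0160). Rows 45708 and 13692 were the 2 rows tested whose genotypes did not overlap on TMM-scaled CPM, where regrouping within series gives 0.101 rows by chance. On CPM of the library total row 45708 was the only 1, against 0.0986 by chance. Row 13692 missed the threshold without NDI1 replicate 1 (edgeR adjusted p = 0.0522), and its adjusted p ranged from 7.23e-06 to 0.592 over 39 alternatives.

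Row 1911 had the next smallest p and did not pass. It measured 11.0 ± 2.38 TMM-scaled CPM in NDI1 livers (SD, n = 8) and 6.52 ± 1.45 in wild-type livers (SD, n = 13), a log2 fold change of 0.79 (SE 0.15, interval 0.49 to 1.09, edgeR adjusted p = 0.0506). It lay above the highest wild-type value in 7 of 8 NDI1 libraries on TMM-scaled CPM, and in 6 of 8 on CPM of the library total. The other 6 of the 10 rows with the smallest p had adjusted p of 0.0645 to 0.0789. Of these, 2 had positive log2 fold changes (0.39 and 1.44) and 4 had negative ones, from -0.93 to -0.47. All 10 had the same sign in both identifier series. They were picked by a fit over both series, which favours such agreement, so it is not independent support.

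Within each series fitted alone, the 2 lower rows had the same sign and did not pass (edgeR adjusted p of 0.147 and 0.492 for row 8821, and 0.243 and 0.592 for row 13692). Row 8821 had a log2 fold change of -0.56 (SE 0.091) in series 1 and -0.44 (SE 0.11) in series 2, and row 13692 had -0.44 (SE 0.082) and -0.28 (SE 0.091). Fitted alone, edgeR called 1 row in series 1, row 45708, with 836 rows at an unadjusted p under 0.05, and 0 rows in series 2, with 951, so row 45708 did not pass in series 2 alone either. The number of called rows also depended on how the mouse identifiers were used. With 6 consecutive runs of identifiers as terms, an alternative chosen after seeing the data, edgeR called 19 rows, including all 3 above. Of the 18 apart from row 45708, 5 were higher and 13 lower in NDI1 livers, with log2 fold changes from -1.05 to 0.69. DESeq2, with the identifier series as the term, called 96 rows, 27 higher and 69 lower, and 92 on the rows that edgeR tested.

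At an unadjusted p under 0.05 the genotype comparison held 1177 rows, or 9.96% of those tested. A uniform spread of p-values would give 591. Splits of the same libraries within series gave up to 2233, and 5 of 100 splits, the real one included, gave 1177 or more. With the 6 identifier runs as terms, chosen after seeing the data, the count was 1736, which 1 of 100 splits within runs, the real one, reached; the highest other gave 1266. Of the 1177 rows, 550 had a positive and 627 a negative log2 fold change. The median log2 fold change over all rows was 0.0013. Most rows were measured closely enough to bound the difference. For 90.7% of rows the 95% interval of the genotype fold lay within 2-fold in either direction, and for 70.4% it lay within 1.5-fold. Among the 1156 rows over 100 CPM these shares were 98.5% and 93.1%, and among the 527 rows under 1 CPM they were 54.3% and 3.61%. Excluding row 45708, 14 rows had an interval wholly beyond 1.5-fold; these intervals are not adjusted for the number of rows. In counts simulated for the genotype comparison over 11814 rows, the same test recovered 52% of rows changed by 1.5-fold, 76% at 2-fold and 94% at 4-fold. That simulation made 120 calls against 3 in the real fit, so its adjusted threshold fell at a larger unadjusted p. It also held no differences between series or runs. The recovered shares may therefore be too high for the real comparison.

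**Figure D2:**
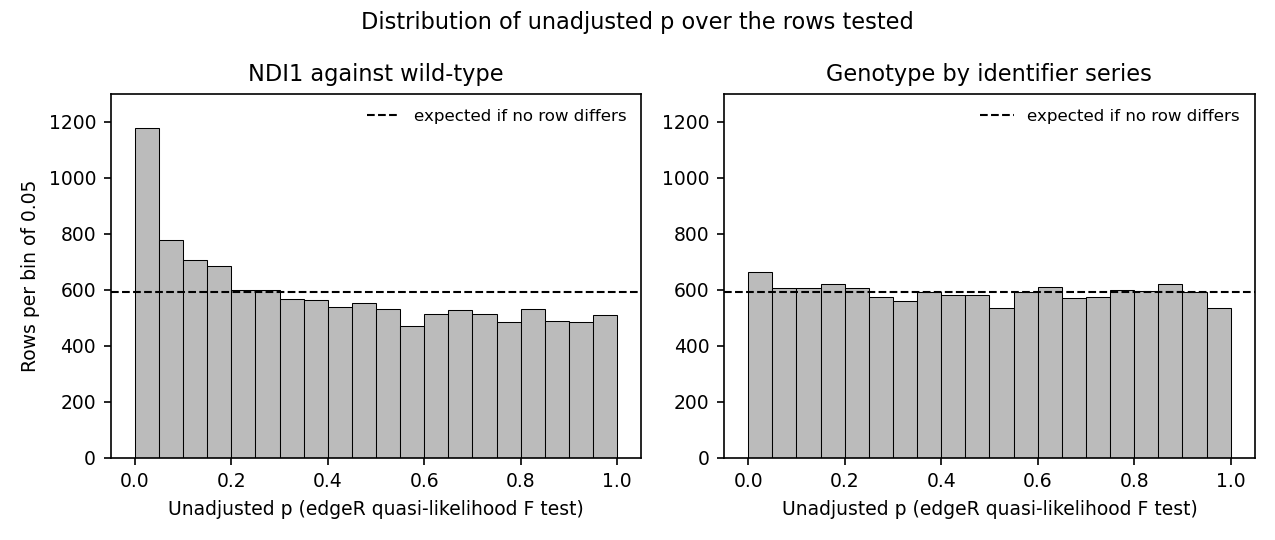
Number of rows (vertical axis) in bins of 0.05 of the unadjusted p (horizontal axis) for the genotype comparison, left, and for the genotype by identifier series term, right, over the 11814 rows tested. The dashed line marks the 591 rows per bin expected if no row differed; the lowest bin holds 1177 rows on the left and 662 on the right.

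The genotype difference was compared between the identifier series with an interaction term. No row passed: edgeR's quasi-likelihood test called 0 of 11814 rows, with 662 at an unadjusted p under 0.05 and a smallest adjusted p of 0.427. DESeq2 called 6 rows for the same term, with 864 at an unadjusted p under 0.05. The edgeR test recovered 36% of simulated 2-fold and 74% of simulated 4-fold interactions, so most 2-fold interactions were not detectable. That simulation made 63 calls against 0 in the real fit and held no other differences between series or runs. Its recovered shares may therefore be too high for the real term. Across the rows tested apart from row 45708, the folds of the 2 series, which share no library, correlated with a Pearson r of 0.148 and a Spearman rho of 0.166. This is a correlation across rows, which are not independent replicates. It was below the 95th percentile of 0.172 in 2000 permutations of genotype within series (one-sided permutation p = 0.0835), and 56.1% of rows had the same sign in both.

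Far more rows passed the threshold between the identifier series than between the genotypes. With genotype as a term, edgeR called 722 rows, 6.11% of those tested, of which 400 were lower and the rest higher in series 2. The median log2 fold change was 0.32 for the higher and -0.39 for the lower rows, and 38 of the higher and 18 of the lower rows changed by more than 2-fold. The higher row with the largest test statistic measured 1011 ± 85.0 TMM-scaled CPM in series 1 (SD, n = 10) and 1868 ± 254 CPM in series 2 (SD, n = 11), with an edgeR adjusted p of 7.17e-08. The corresponding lower row measured 36.5 ± 13.0 TMM-scaled CPM in series 1 (SD, n = 10) and 0.488 ± 0.697 CPM in series 2 (SD, n = 11), with an edgeR adjusted p of 6.16e-07. Series 2 was also the shallower series.

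**Figure D3:**
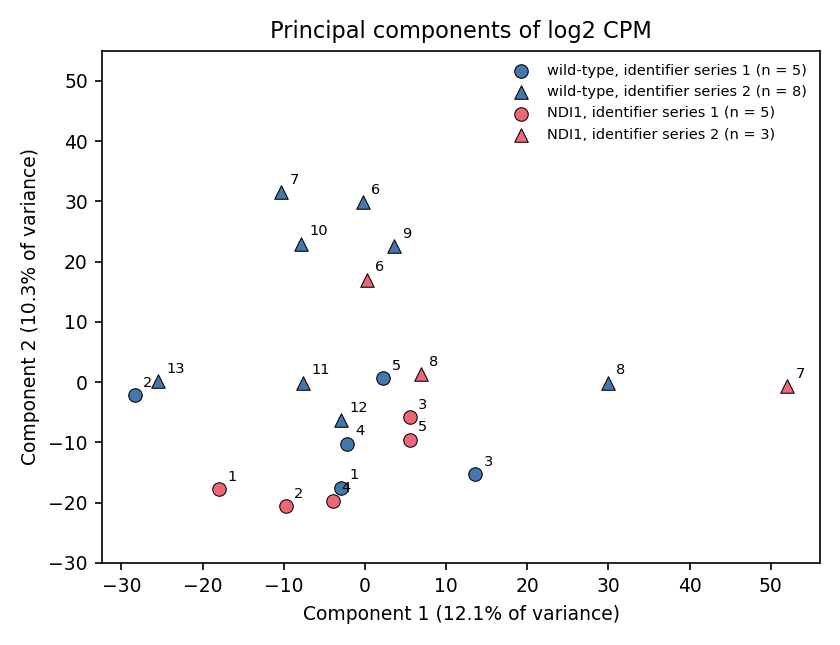
Scores of the 21 libraries on principal components 1 (horizontal, 12.1% of variance) and 2 (vertical, 10.3% of variance) of log2 CPM, with replicate numbers beside the points. The genotypes (colours) are mixed along both axes, and NDI1 replicate 7 has the highest score on component 1, 52.0 against 29.9 for the highest wild-type library.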

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

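The tests of row 45708 against other rows and of a single library, the count of small p-values itself and the use of identifier runs were chosen after the results were seen. The predictions for the splits and for the correlation between series were written before their results; the wording of the partner search and the reading of the correlation between series were also changed after their results.

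Row 45708 was counted in all 8 NDI1 libraries and in none of the 13 wild-type libraries. On/off counting of near-identical rows that fell on the genotype by chance is argued against: of all rows 364 were at 0 in exactly 13 libraries, with any count in the other 8, and together they matched 92 of the 41580 regroupings of genotype within series (0.221%), the real one included. A transcript carried by the NDI1 mice alone was not tested beyond the counts that prompted it: 0 other rows at 0 in at least 3 libraries and with 20 or more counts in every other followed the genotype, which neither favours nor excludes it. The NDI1 transgene is a candidate source of these counts, as a hypothesis, and so is another sequence carried with it, since the table names neither. The level was 3.14-fold higher in series 1 than in series 2 among the NDI1 libraries (exact two-sided permutation p = 0.0357). This singled it out because both series are under the same contrast. On mean log2(CPM + 0.5) its difference between the series was 1.70. Of 5977 rows of 5 to 50 CPM in NDI1 livers, 15 (0.251%), row 45708 included, differed as much on that scale. All NDI1 mice of series 2 belong to 1 identifier run, so this difference cannot be told apart from differences between runs.

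The 1177 rows at an unadjusted p under 0.05 between genotypes were reached by 5 of 100 splits of the libraries within series, the real one included, with 2233 in the highest other split, so chance cannot be excluded. With any 1 library left out the count stayed above the number that a uniform spread of p-values gives. The lowest was 945, without NDI1 replicate 8, against 604 among the 12078 rows that fit tested. This ratio of 1.56 was only just over a limit set after the results were seen. Some splits of all the libraries also gave more than 945, so a single library as the whole source stays undecided. Differences between runs of mouse identifier numbers are argued against as the whole source, since with the runs as terms the count was 1736; 1 of 100 splits within runs, the real one, gave as many, and the highest other gave 1266. A genotype difference shared by both identifier series cannot be told apart from chance: the correlation of their folds had a one-sided permutation p of 0.0835, which missed the threshold set beforehand, but r was 0.148 against a 95th percentile of 0.172 and a median of 0.0025 in permutations, with 3 NDI1 libraries in series 2, so missing that bar does not show its absence. A small genotype difference in many rows, partly hidden by differences between runs, stays open as a hypothesis.

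Rows that alternated between 0 and large counts (at 0 in at least 3 libraries, 20 or more in every other) numbered 14, with maxima of 87 to 734 counts, and 0 followed the identifier series. For counts passed to and from a single partner row, no close match was found. Of the 14, 0 had a row falling as they rose (r under -0.9 and a slope between -2 and -0.5), and 0 did in any of 100 permutations. The lowest r for any of the 14, at any slope, was -0.852. The simulated pairs that checked the search mirrored their rows with little noise. A partner with noisier counts could be missed, so the search does not decide this explanation. Exchange among several rows, or with a far more abundant row, was not tested, and no biological explanation was tested.

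NDI1 replicate 7 stood apart from the other NDI1 libraries on principal component 1, with a score of 52.0 against 6.88 for the next; a library was singled out in 1 of 10 measures tested among the NDI1 libraries, and chance alone gives 0.5 on average.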

How the results depend on the processing

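The fits with identifier runs, DESeq2 on the rows edgeR tested, limma-voom without weights, the counts at an unadjusted p and the alternatives for single rows were chosen after the data were seen. Rows 45708, 8821 and 13692 were all called under each change of scaling and of filter, in DESeq2, in limma, without the series term and with a surrogate variable. The count of 3 genotype calls became 5 without a low-count filter, 11 with limma-voom and sample quality weights (8 without the weights), 96 with DESeq2 on every row with a count (92 on the rows edgeR tested), 13 at an adjusted p under 0.1, 1 in series 1 alone, 0 in series 2 alone (edgeR; 951 at an unadjusted p under 0.05) and 19 with identifier runs as terms. The single-series fits hold fewer libraries; for the others the cause was not tested. With 1 library left out the count ranged from 2 to 6: 6 without NDI1 replicate 6, and 5 without NDI1 replicate 7, wild-type replicate 6 or wild-type replicate 8. Replicate numbers 1 to 8 occur in both genotypes but did not pair the libraries: 4 of 8 same-numbered pairs had a correlation of deviations over 0.1 (range -0.051 to 0.19), and 2 of 8 NDI1 libraries correlated best with their own number. These deviations keep the difference between the series. After its removal the correlations of the 8 same-numbered pairs ran from -0.18 to 0.078. With the numbers as a replicate block on 16 libraries edgeR called 2 rows, and 2 on the same libraries without it; row 13692 was lost in both (edgeR adjusted p = 0.235 and 0.0566), as it was without NDI1 replicate 1 (0.0522), with log2 fold changes of -0.39, -0.39 and -0.35 against -0.37; these fits hold fewer libraries. Row 8821 passed in 37 of 39 alternatives, row 13692 in 34 and row 1911 in 12 (adjusted p from 0.000424 to 0.555), and none changed sign. Rows at an unadjusted p under 0.05 numbered 2004 without a filter, which tests more rows, and 945 to 1256 with 1 library left out. For the interaction DESeq2 called 6 rows where edgeR called 0; the cause was not tested. The series comparison called 722 rows, 692 with DESeq2 size factors and 486 without a filter. The smallest simulated genotype changes, under 1.5-fold, were mostly not detectable at these depths (12% recovered). The sex index, gene list, position and metadata-column alternatives were not run.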

Other observations

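The comparisons of identifier runs were chosen after 1 other split of the libraries had called many rows; the predictions for the other splits were written before their results.

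For the 3 rows changed by genotype, 2 of 100 splits within series called as many, the real one included, which is under 0.05 for that count. The count includes row 45708, so the splits say little about rows 8821 and 13692 by themselves. They also treat mice of different identifier runs as exchangeable, which the run differences below call into question. The other split that called as many called 247 rows and points to a structure of the samples. In series 2 it set wild-type replicates 11 to 13, the mice with the highest identifier numbers, against the rest. In series 1 it set NDI1 replicate 1 and wild-type replicates 1 to 4 against the rest. For the 96 rows called by DESeq2, 2 of 40 splits called as many, with 383 in the highest other, so chance cannot be excluded for that count. For the 722 rows between series, 1 of 100 splits, the real one, called as many, and the highest other called 148. This excludes chance only if single mice are exchangeable between the series. Each identifier run lies within a single series, so these splits cannot tell a series difference from differences between runs. For the interaction the splits decide nothing, since 100 of 100 necessarily reach its 0 calls in edgeR; the highest other called 14. For that term 662 rows had an unadjusted p under 0.05, and DESeq2 called 6.

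Wild-type mice of series 2 differed by identifier run, a run ending where the numbers skip by more than 3. Between wild-type replicates 11 to 13 (n = 3), whose runs hold 0 NDI1 mice, and replicates 6 to 10 (n = 5), edgeR's quasi-likelihood test called 212 of 11583 rows, 128 higher and 84 lower in the former. Of 56 splits of these 8 libraries, 1, the real one, called as many, and the highest other called 2. This contrast was picked because the split above had singled out the same 3 libraries, so its count of splits is not independent evidence. Leaving them out gave 3 genotype calls, the same 3 rows.

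With the 6 identifier runs as terms, edgeR called 19 rows between genotypes. Of 100 splits within runs, 1, the real one, called as many, and the highest other called 2. The fit was picked after seeing the data and is 1 of 39 alternatives, so this rank does not by itself exclude chance. The 19 rows also include row 45708. Apart from row 45708, 5 rows were higher, with log2 fold changes from 0.21 to 0.69, and 13 were lower, from -1.05 to -0.33; 1 of these 18 exceeded 2-fold. All 18 had the same sign with the identifier series as the term, where their unadjusted p in edgeR was at most 0.0599. Both fits use the same libraries, so this agreement is not independent support. Whether the runs stand for litters, cages or days is not given in the sources used here.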
